A study of Mus musculus with 16 samples.

How the data were processed

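H3K27 acetylation, a histone mark of active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in livers of mice whose strain background is labelled C57BL/6J, for both genotypes. Per the labels, wild-type (WT) and NCoR1 knockout (KO) mice received either chow or a diet low in iodine with 0.15% propylthiouracil (PTU/LID) from 6 weeks of age for 3 weeks, and livers of all groups, chow included, were collected on day 21. Propylthiouracil blocks the synthesis of thyroid hormone. The labels list 16 libraries, of which 12 are H3K27ac libraries in 4 groups of 3 and 4 are input libraries; the input libraries are not analysed here. Each H3K27ac library carries its own number in its title and no number is shared between groups, so no pairing was used. Libraries are named here by their titles in the labels, so that Chow_WT_27ac_96 is a WT chow library and Ptulid_NCoRKO_27ac_211 a KO library on PTU/LID. The labels do not state that each number is a separate animal, so p-values measure the spread between these libraries.

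The counts are those the authors deposited: 1 table of whole-number read counts per library over 52645 regions shared by the 12 H3K27ac libraries. Per the submitters' processing notes, the build was mm10 and the tools bcl2fastq 2.17.1.14, Bowtie2 2.2.1, Picard 2.8.1, MACS2 2.1.1 and bedtools 2.26.0, with no roles or order. How the shared regions were made, whether the caller ran per library or on pooled reads, and whether duplicates were removed are not given in the sources used here. The deposited table also gives a length for each region, which equals its end minus its start, so starts count from 0 and were printed here as 1-based positions. The lowest count in the table is 1, and no region of any library is at 0. Region lengths run from 200 to 9857 base pairs with a median of 468. The table keeps 4 regions on the mitochondrial chromosome, chrM, and 10 nuclear regions followed them across libraries with a correlation above 0.9. Reads of copies of mitochondrial DNA in the nuclear genome cannot be told from mitochondrial reads there. These regions stayed in the counts, and leaving them out was an alternative.

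Regions were assigned to genes with a RefSeq table of GRCm38.p6, the assembly of mm10, which gives the start and end of 21900 protein-coding genes but no strand or exons. A region belonged to the gene that contains its midpoint, or otherwise to the gene with the nearest annotated end within 50 kb. Nearest transcript starts had been planned, which a table without strand cannot give, so both ends of a gene were treated alike and exons, introns and untranslated regions were not told apart. For the same reason the planned promoter setting became regions within 2.5 kb of either gene end. In all, 11458 genes received a region. Counts were also summed over the regions of each gene.

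The tests were run with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test with robust estimates and 1 mean per group, over all 12 libraries, which share 1 estimate of the spread. TMM factors came from the region counts or, at gene level, from the counts summed per gene. Features were kept by filterByExpr with its minimum count of 10, which left 52606 regions and 11446 genes. Benjamini-Hochberg adjusted p below 0.05 counted as passing. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of the F statistic. Group means and SDs are in CPM, counts scaled to library size with TMM factors, with 3 libraries each. At gene level the library size is the sum over genes, so CPM of genes and of regions are on different scales. Levels of H3K27ac are relative to the sum of the counts in these regions, so a change of the whole mark cannot be seen.

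The tests, the gene lists, the rule for named regions and genes, and the alternatives not marked as added were fixed before the data were examined. The 21 gene lists with 378 entries came from textbook knowledge: genes induced by thyroid hormone, lipogenesis, cholesterol synthesis and uptake, bile acid synthesis and transport, fatty acid oxidation and PPARα targets, glucose metabolism, xenobiotic metabolism, the circadian clock, nuclear receptors with their corepressors and coactivators, the growth hormone axis, male-biased and female-biased liver genes, inflammation and acute phase, cell cycle, hepatocyte identity, housekeeping, and markers of Kupffer cells and macrophages, lymphocytes, endothelial cells, stellate cells and fibrosis, and cholangiocytes. Lists were tested with camera in limma 3.58.1 on the gene-level counts, with a preset correlation of 0.01, over 105 combinations of list and comparison. Of these, 47 passed, and 0 passed with a correlation estimated per list; 31 passed with fry, which asks whether the genes of a list move, on balance, one way. Regions called in one comparison were looked up in another with fry, adjusted over 20 such tests. The adjusted p with an estimated correlation is given beside each list.

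Regions were named by rule. For each comparison of 2 groups these were up to 8 higher and 8 lower regions with the largest fold change among those that passed, with mean level at or above the median region, no overlap between the 3 and 3 libraries, and 1 region per gene, leaving out genes with clone-type names. Where fewer than 3 regions had passed one way, the 3 with the smallest p would have been named, which was not needed. For the interaction and for the mean effects up to 5 each way were taken. From each list with a passing test or member, up to 4 members with the smallest p were taken, and Ncor1, Thrb, Thra, Thrsp, Dio1, Me1 and Fasn were always reported. Some list members that this rule names are not reported here. With no overlap as a criterion, chance alone separates 3 from 3 libraries in 10% of regions. Mup, Sult2a and Cyp3a genes are families of near-identical copies, and reads may be shared between their members.

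Pairs of libraries of 1 group were checked for repeats by chi-square per degree of freedom over regions with at least 20 counts, which was between 1.949 and 4.183. Total counts per library were between 2965505 and 7416187, and the median count per region was between 29 and 62. On 5 simulated data sets for PTU/LID against chow in WT, with 200 features changed in each, 35.8% of regions changed 2-fold and 4.4% of those changed 1.5-fold were recovered among 52606 regions, and 7.8% of the calls were false. At gene level, over 11446 genes, these shares were 79.8%, 43.8% and 5.2%. These simulations changed fewer features than the 1949 regions and 880 genes called in the data. They also held no structure among libraries beyond depth, so recovery and false calls in the data may differ. On 5 simulated data sets for KO against WT on chow, the lipogenesis list, shifted by 0.4 on the log2 scale, passed 5 times, and 0 of the 90 tests of lists that share no gene with it passed. Of 10 tests of the 2 lists that do share genes with it, 4 passed, so lists with common genes are not independent. Genes were drawn independently of each other in these data sets. They therefore cannot show how often lists of correlated genes pass without a shift.

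The alternatives fixed in advance were DESeq2 size factors in edgeR, library totals without TMM, cyclic loess with limma, no filter on low counts, the DESeq2 1.42.0 Wald test, fits of only the groups compared, regions at gene ends or within 10 kb for the gene level, each library left out in turn, lists tested with an estimated correlation, with fry or over regions in place of genes, and a threshold of 0.01 for regions carried from one comparison to another. Alternatives chosen after seeing the data had a term for 2 sets of libraries parted at 2% of counts on chrM, no chrM-like regions, library totals after removing those regions, and cyclic loess at gene level. The 2% division and the tests on regions near Ncor1 and on marker lists were also chosen after seeing the data. Counts were compared with other groupings of the same libraries, all 10 splits for each comparison of 3 with 3, and 25 draws, the real grouping included, for the interaction and the mean effects, a number set by run time. A correction for GC content and a comparison with input were planned but not run, because no genome sequence and no input counts were used here.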

Results

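H3K27 acetylation (H3K27ac), a histone mark of active promoters and enhancers, was profiled by ChIP-seq in livers of wild-type (WT) and NCoR1 knockout (KO) mice. They received chow or PTU/LID, a diet low in iodine with propylthiouracil. No thyroid hormone values were used here, so thyroid state was not checked. Sex and time of day of collection were not used either. Group differences in these were therefore not checked for the sex-biased and clock lists. NCoR1 is a corepressor that unliganded nuclear receptors, among them the thyroid hormone receptors, recruit with histone deacetylase 3. There were 3 H3K27ac libraries in each of the 4 groups. Total counts over the 52645 regions ranged from 2965505 in library Chow_WT_27ac_96 to 7416187 in library Ptulid_NCoRKO_27ac_232. They averaged 4087936 ± 1530534 (SD, n = 3) in WT on chow, 4123762 ± 895028 in WT on PTU/LID, 6347161 ± 622157 in KO on chow and 6073347 ± 2045496 in KO on PTU/LID. Of the nuclear regions, 43.6% lay inside a gene, 33.8% within 2.5 kb of a gene end, 15.9% between genes and 6.7% more than 50 kb from a gene.

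Ncor1 itself, on chromosome 11, had 6 regions between positions 62351299 and 62457105 of mm10. Their summed counts gave a gene-level 54.97 ± 9.34 CPM in WT on chow (counts scaled to library size, SD, n = 3), 55.25 ± 7.18 in WT on PTU/LID, 53.9 ± 9.46 in KO on chow and 54.08 ± 5.81 in KO on PTU/LID. The log2 fold change of KO against WT was -0.02 ± 0.16 (SE) on chow and -0.03 ± 0.16 on PTU/LID, neither of which passed. The labels do not name the deleted part, so acetylation of Ncor1 does not check the genotype of any library. No NCoR1 RNA or protein values were used here. How far, and in which liver cells, NCoR1 was lost was therefore not checked. The thyroid hormone receptor genes Thrb and Thra also passed in no comparison, with log2 fold changes of KO against WT on PTU/LID of 0.12 ± 0.1 and -0.06 ± 0.18.

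The first principal component over nuclear regions, with 23.4% of the variance, placed PTU/LID libraries above chow libraries, and the second, with 17.9%, placed each KO group above the WT group on the same diet. The share of counts on the mitochondrial chromosome, chrM, parted the libraries into 2 sets that cut across the groups. It was between 2.27% and 17.25% in 7 libraries (Chow_WT_27ac_96 and Chow_WT_27ac_99, Ptulid_WT_27ac_135, all 3 of KO chow, and Ptulid_NCoRKO_27ac_211) and between 0.72% and 1.08% in the other 5. It averaged 1.5% in the PTU/LID libraries and 5.94% in the chow libraries (2-sided exact permutation test, 6 against 6, p = 0.0281, adjusted p = 0.0843 over 6 such tests). Within each group that held both sets, libraries of higher chrM share lay lower on the first component. They had -57.6 and -52.5 against -42.6 in WT on chow, and -3.4 against 43.1 and 44 in WT on PTU/LID. In KO on PTU/LID it was 21.1 against 63.7 and 66.7, so this component does not carry diet alone. These libraries also had lower total counts than the others of their group. On the second component Ptulid_NCoRKO_27ac_211 lay at -1.5 against 29.4 and 30.2, and Ptulid_WT_27ac_135 at -54.1 against -36.2 and -46.2. In WT on chow the higher set had -19.7 and -28.4 against -24.6. WT libraries lay lower on PTU/LID than on chow, so the second component does not carry genotype alone. Total counts averaged 6210254 in KO and 4105849 in WT (exact permutation p = 0.0195, adjusted p = 0.0843). In pairs of libraries of 1 group, chi-square per degree of freedom was 1.949 to 4.183, so no pair agreed within sampling noise.

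**Figure D1:**
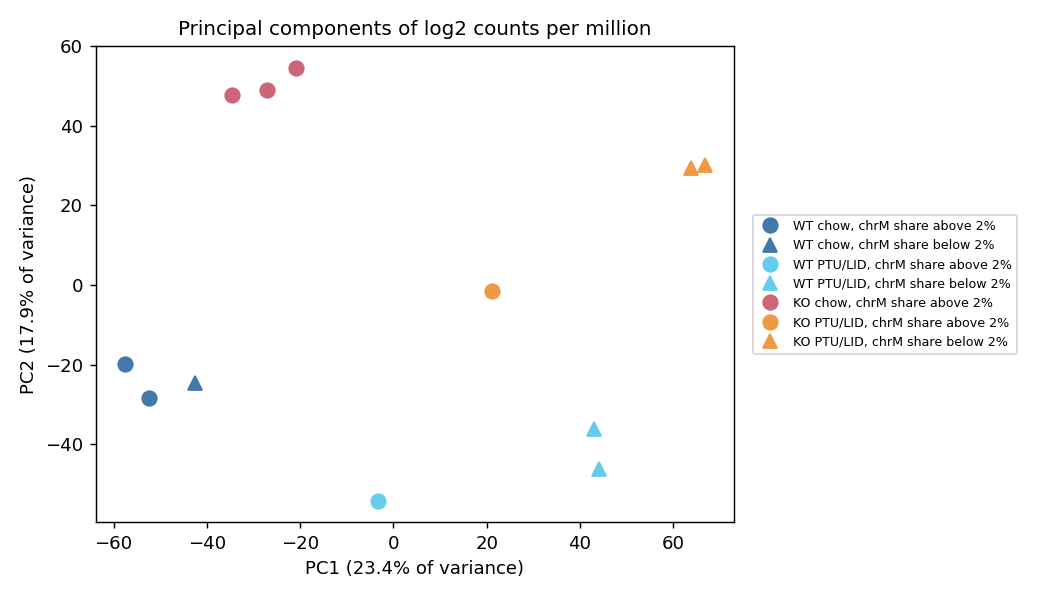
Each point is 1 of the 12 H3K27ac libraries, placed by its scores on the first (23.4% of variance) and second (17.9%) principal components of log2 CPM over nuclear regions, with colours for the 4 groups, circles for libraries with more than 2% of counts on chrM and triangles for the others. PTU/LID libraries lie at -3.4 or above on the first component and chow libraries at -20.8 or below.

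To ask what the PTU/LID diet does to liver acetylation, it was compared with chow in WT. Named regions that fell included those of the steroid sulfotransferase genes Sult2a7 and Sult2a8, of Mup genes, which encode major urinary proteins, and of Dio1, the deiodinase that makes active thyroid hormone in liver and is itself induced by it. The region 26.4 kb from Sult2a7 (chromosome 7, 14517333 to 14521529) fell from 147.5 ± 15.5 to 21.32 ± 3.46 CPM (SD, n = 3 each; log2 fold change -2.79 ± 0.18 SE, adjusted p = 1.37e-13). Inside Dio1 (chromosome 4, 107301831 to 107302587), acetylation fell from 17.47 ± 3.2 to 3.39 ± 0.44 CPM (log2 fold change -2.39 ± 0.29, adjusted p = 3.83e-07). Of the named regions it rose most 2.3 kb from Thap7 (chromosome 16, 17533206 to 17533717), from 4.26 ± 0.48 to 20.54 ± 7.78 CPM (log2 fold change 2.25 ± 0.32, adjusted p = 2.25e-05). Other named regions that rose belonged to Rgs16, Osbpl5, Bptf, Nav2, Nrg2, Rgs8 and Rtn1, by 1.67 to 1.97 on the log2 scale. Summed over their regions, 2 of 8 Sult2a genes fell, and of 23 Mup genes 19 fell and 1 rose, families picked after their values were seen. The others that fell belonged to Mup2, Mup12, Mup22, Mup-ps12, Sult2a8 and Vmn2r20, with log2 fold changes from -2.59 to -2.36. Sult2a and Mup are families of near-identical copies, so which member carries the change is uncertain.

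Among genes induced by thyroid hormone, 4 of 16 fell and 0 rose (4 and 0 adjusted over the list alone). These were Dio1 (log2 fold change over all its regions -1.94 ± 0.18), the glycerophosphate dehydrogenase gene Gpd2 (-0.7 ± 0.13), Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-0.65 ± 0.14), and malic enzyme, Me1 (-0.62 ± 0.15). The list was lower than other genes (camera, adjusted p = 0.00346, or adjusted p = 0.228 with an estimated correlation). Thrsp had -0.31 ± 0.14 and Fasn 0.15 ± 0.14, neither past the threshold. Without 1 library, the list did not pass (Ptulid_WT_27ac_135 left out, adjusted p = 0.0565), nor did Me1 (Ptulid_WT_27ac_155 or Ptulid_WT_27ac_280 left out, 0.084 and 0.103). Over regions at gene ends Gpd2 had an adjusted p of 0.1, with 0.000246 to 0.1 over its alternatives.

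Of 21 genes of bile acid synthesis and transport, 5 fell (6 adjusted over the list alone, adjusted p = 0.0231, or adjusted p = 0.429 with an estimated correlation). These included the uptake transporter Slco1a1 (-1.56 ± 0.3) and Abcb4, which moves phospholipid into bile (-0.55 ± 0.11). Of 13 genes of the growth hormone axis, Prlr, Stat5a and Ghr, which encode the prolactin receptor, a factor that growth hormone activates and the growth hormone receptor, fell (5 adjusted over the list alone, adjusted p = 0.00248, or adjusted p = 0.228 with an estimated correlation). Ghr took the opposite sign, 0.09, over regions at gene ends (-0.51 to 0.09 over its alternatives), where the list did not pass (adjusted p = 0.115) and Prlr had -0.16 and did not pass; with cyclic loess Ghr did not pass. Male-biased genes were lower (adjusted p = 0.0183, or adjusted p = 0.228 with an estimated correlation), with 4 of 15 lower and 2 higher (5 and 3 adjusted over the list alone), and Mup1 fell by 1.74 ± 0.14 on the log2 scale. Female-biased genes were also lower, with 1 of 18 past the threshold, Abcd2, a peroxisomal transporter (1 adjusted over the list alone, adjusted p = 0.0154, or adjusted p = 0.433 with an estimated correlation). The bile acid and female-biased lists did not pass over regions at gene ends (medians -0.025 and -0.159) or with fry. Some of these calls were lost with 1 library left out. The bile acid list did not pass without Chow_WT_27ac_106 or Ptulid_WT_27ac_280 (adjusted p = 0.0715 and 0.0752 as the lowest and highest), nor the female-biased list without Chow_WT_27ac_96 or Ptulid_WT_27ac_135 (0.0546 to 0.119). The gene Prlr was lost without Chow_WT_27ac_96 or Chow_WT_27ac_99 or Ptulid_WT_27ac_280 (0.0527 to 0.0736), Stat5a without Chow_WT_27ac_96 or Ptulid_WT_27ac_280 (0.0846 to 0.105), Ghr without Chow_WT_27ac_96 or Ptulid_WT_27ac_155 (0.102 to 0.111), and Abcd2 without Chow_WT_27ac_96 or Chow_WT_27ac_99 or Ptulid_WT_27ac_155 or Ptulid_WT_27ac_280 (0.0509 to 0.0848).

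Glucose metabolism was higher in WT on PTU/LID, with 6 of 20 genes that rose (9 adjusted over the list alone, with 1 lower; adjusted p = 0.0265, or adjusted p = 0.505 with an estimated correlation). Among them was the pyruvate kinase gene Pklr (0.62 ± 0.14). Clock genes were higher (2 of 19, the same number adjusted over the list alone, adjusted p = 0.0165, or adjusted p = 0.433 with an estimated correlation). Per2, a repressor of the clock, rose by 0.51 ± 0.11. Hepatocyte identity genes were higher, with 4 of 21 that rose, such as Ttr, the thyroid hormone carrier transthyretin (0.43 ± 0.09; 5 adjusted over the list alone, adjusted p = 0.000663, or adjusted p = 0.399 with an estimated correlation). Of the markers of other liver cells, the Kupffer cell and endothelial lists were lower. For Kupffer cells and macrophages, 1 of 8 genes fell, Spi1, a myeloid transcription factor (-0.91 ± 0.19; 5 adjusted over the list alone, median -0.81; adjusted p = 0.00248, or adjusted p = 0.223 with an estimated correlation). For endothelial cells, 2 of 13 fell, Pecam1 and Ehd3 (3 adjusted over the list alone, median -0.41; adjusted p = 0.00245, or adjusted p = 0.345 with an estimated correlation). The glucose list did not pass without Chow_WT_27ac_96 or Chow_WT_27ac_99 or Ptulid_WT_27ac_155 or Ptulid_WT_27ac_280 (adjusted p = 0.0518 to 0.179) or with the chrM-set term (0.127), cyclic loess (median 0.094), fry or regions in place of genes (median 0.044), nor the clock list with fry or without Chow_WT_27ac_96 or Ptulid_WT_27ac_155 (0.0596 to 0.0737). Pklr was lost without Chow_WT_27ac_99 or Ptulid_WT_27ac_155 or Ptulid_WT_27ac_280 (0.0505 to 0.0774), Pecam1 without Chow_WT_27ac_106 or Ptulid_WT_27ac_155 or Ptulid_WT_27ac_280 (0.0515 to 0.0762), and Ehd3 without any but Ptulid_WT_27ac_135 (0.0529 to 0.198). Over regions at gene ends Ttr (log2 fold change 0.34) and Ehd3 (-0.43) did not pass.

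The other lists did not pass in WT by diet, with adjusted p of 0.863 for lipogenesis (1 gene up, 2 down of 22), 0.524 for cholesterol (1 down of 23) and 0.851 for fatty acid oxidation (2 up, 1 down of 29). It was 0.842 for xenobiotic metabolism (2 up, 1 down of 21) and 0.524 for receptors and coregulators (0 of 17). They were 0.286 for inflammation (2 up of 13), 0.425 for cell cycle (1 up, 1 down of 7), 0.303 for lymphocytes (1 down of 3), 0.234 for stellate cells (0 of 7), 0.234 for cholangiocytes (1 up of 5) and 0.449 for housekeeping genes (2 up of 12). Members that passed and kept their call with any 1 library left out were Cyp3a11, a drug-metabolizing cytochrome P450 (-0.81 ± 0.12), Sc5d, a sterol desaturase (-0.48 ± 0.11), the T cell marker Cd4 (-1.01 ± 0.18) and the chemokine gene Ccl2 (0.92 ± 0.17). Ccl2 took the opposite sign over regions at gene ends (-0.11) and within 10 kb (-0.08), with -0.11 to 0.98 over its alternatives, and Sc5d did not pass over regions at gene ends (-0.42). In all, 43 list genes named by rule passed in WT, and 29 of them were lost when 1 or more of the 6 libraries was left out.

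In all, 1949 of 52606 regions differed in WT (952 higher, 997 lower) and 880 of 11446 genes (480 higher, 400 lower). The count changed with every library left out, where fewer libraries also give less power. It was 988, 906 and 1177 regions without Chow_WT_27ac_96, Chow_WT_27ac_99 and Chow_WT_27ac_106, and 3612, 932 and 669 without Ptulid_WT_27ac_135, Ptulid_WT_27ac_155 and Ptulid_WT_27ac_280, with 491, 398, 466, 1582, 376 and 337 genes in the same order. Within the libraries of lower chrM share (2 PTU/LID against 1 chow) 1891 regions differed (871 higher, 1020 lower). Within those of higher share (1 against 2) it was 484 (180 higher, 304 lower), where a lone library is assumed to vary like the others.

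**Figure D2:**
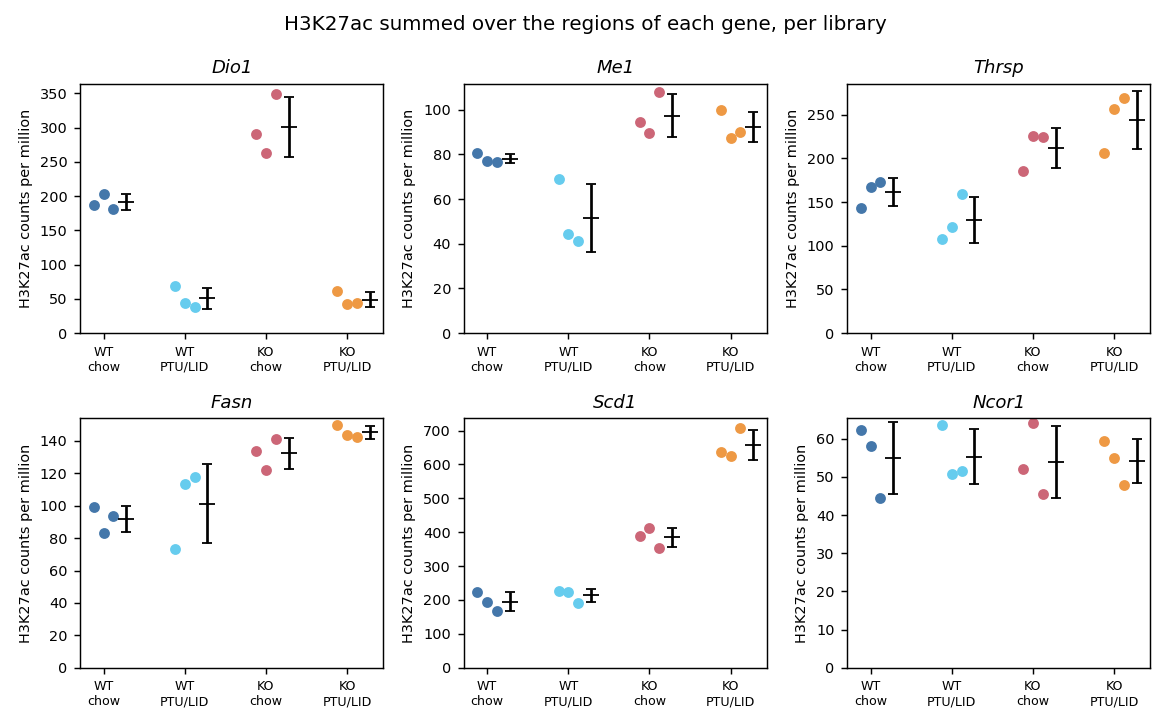
Acetylation of 6 genes in gene-level CPM, from counts summed over each gene's regions, with 1 point per library (3 per group) and bars for the group mean and SD. Dio1 averaged 190.7 and 300.4 CPM on chow and 50.47 and 48.91 on PTU/LID, in WT and KO respectively.

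The same diet comparison in KO asks whether the effect is present in the knockout. Dio1 fell again, by 2.64 ± 0.18 on the log2 scale over its regions (adjusted p = 1.13e-08), from 300.4 ± 43.86 to 48.91 ± 10.86 CPM (SD, n = 3 each). The largest named loss was in Mup-ps12 (chromosome 4, 61441960 to 61447886; 395.0 ± 63.86 to 38.3 ± 5.51 CPM; log2 fold change -3.37 ± 0.19, adjusted p = 1.23e-15). Next came an end of Cyp3a16 (chromosome 5, 145468718 to 145469639; -3.31 ± 0.29, adjusted p = 4.97e-10), both of families with near-identical copies. Other named regions that fell belonged to Dio1, Mup9, Mup10, Mup11, Mup17 and Akr1d1, a bile acid reductase (-2.86 ± 0.26). A region at an end of Osbpl5 (chromosome 7, 143755622 to 143756577) rose from 3.88 ± 1.68 to 26.9 ± 8.72 CPM (log2 fold change 2.8 ± 0.32, adjusted p = 9.91e-07). The others that rose belonged to Iqck, Khdc1a, Kcnk3, Gsta3, Stab2, Oma1 and Ppargc1a, a coactivator of gluconeogenic genes, by up to 2.74. The Stab2 region did not pass with a term for the chrM sets (adjusted p = 0.0664; 8.6e-10 to 0.0664 over its alternatives) or without Chow_NCoRKO_27ac_122 (0.0566).

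Of the 16 genes induced by thyroid hormone, 5 fell and 1 rose in KO (5 and 1 adjusted over the list alone), with Cyp7a1 at -1.0 ± 0.13, Idh3a, of the citric acid cycle, at -1.2 ± 0.23 and Gpd2 at -0.55 ± 0.12. As a list they did not pass (median -0.02, mean -0.27, adjusted p = 0.125, or adjusted p = 0.472 with an estimated correlation). With fry they did, downward (adjusted p = 0.042). The mean in WT was -0.31, and the interaction did not pass for this list (camera, adjusted p = 0.532). Me1 had -0.08 ± 0.14. Lipogenic genes were higher, with Scd1, the stearoyl-CoA desaturase (0.77 ± 0.11), and Acly, which makes cytosolic acetyl-CoA (0.55 ± 0.12), up and Fads2 down among 22 (2 and 1 adjusted over the list alone, adjusted p = 0.0134, or adjusted p = 0.345 with an estimated correlation). Fatty acid oxidation was higher (2 of 29, Acot1, an acyl-CoA thioesterase, and Acadm, an acyl-CoA dehydrogenase; 2 adjusted over the list alone, adjusted p = 0.0168, or adjusted p = 0.575 with an estimated correlation). Glucose metabolism was higher (1 of 20, Ppargc1a; 1 adjusted over the list alone, adjusted p = 0.00027, or adjusted p = 0.345 with an estimated correlation). Hepatocyte identity was higher (2 of 21, Ttr and Apoa2; 3 adjusted over the list alone, adjusted p = 0.0129, or adjusted p = 0.501 with an estimated correlation). Male-biased genes were lower (5 of 15 down, 1 up; 5 and 3 adjusted over the list alone, adjusted p = 0.00248, or adjusted p = 0.164 with an estimated correlation). Female-biased genes were lower (5 of 18; 7 down and 1 up adjusted over the list alone, adjusted p = 0.00346, or adjusted p = 0.345 with an estimated correlation), among them Cyp3a16 (-2.45 ± 0.26) and Abcd2 (-0.58 ± 0.11). With the chrM-set term the lists of lipogenesis, fatty acid oxidation, glucose metabolism and hepatocyte identity did not pass (adjusted p = 0.211, 0.36, 0.0732 and 0.486), nor did fatty acid oxidation without Chow_NCoRKO_27ac_122 or Ptulid_NCoRKO_27ac_232 or Ptulid_NCoRKO_27ac_239 (0.053 to 0.237) or over regions in place of genes (median 0.084). With cyclic loess lipogenesis, fatty acid oxidation and hepatocyte identity did not pass (medians 0.076, 0.09 and 0.117), and with fry fatty acid oxidation, glucose metabolism and hepatocyte identity did not. Over regions at gene ends Ttr (log2 fold change 0.36), Acadm (0.34) and Apoa2 (0.41) did not pass. Fads2 did not pass with the chrM-set term or within 10 kb, Ppargc1a with the chrM-set term, and Apoa2 with that term or cyclic loess.

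Kupffer cell markers had a median of 0.09 by diet in KO (adjusted p = 0.863) and endothelial markers -0.15 (1 down of 13; adjusted p = 0.423). Bile acid genes had an adjusted p of 0.0749 (2 down of 21, Cyp7a1 and Akr1d1), xenobiotic genes 0.0543 (3 up of 21), and clock genes 0.0727 (0 of 19; 3 adjusted over the list alone). Akr1d1 had -0.87 over all its regions, but -0.34 over those at gene ends and -0.09 within 10 kb, where it did not pass. Cdkn1a, an inhibitor of the cell cycle, rose by 1.28 ± 0.16, in a list with a median of -0.008, a mean of 0.088 and an upward test (adjusted p = 0.903). Igfbp1, a growth hormone axis gene that binds insulin-like growth factors, rose by 0.62 ± 0.12 (1 up, 1 down of 13; adjusted p = 0.558 for the list). Gstm3, a glutathione transferase, rose by 0.89 ± 0.19, and Cd4 fell by 1.03 ± 0.16 on the log2 scale (1 of 3 lymphocyte markers; adjusted p = 0.134). Adjusted p was 0.842 for cholesterol (0 of 23), 0.905 for receptors and coregulators (1 up of 17), 0.247 for inflammation (2 up, 1 down of 13), 0.607 for stellate cells (0 of 7), 0.443 for cholangiocytes (0 of 5) and 0.84 for housekeeping genes (0 of 12). Of the 33 list genes named by rule that passed in KO, 14 were lost when 1 or more of the 6 libraries was left out. Among those named here these were Fads2 without any but Ptulid_NCoRKO_27ac_211 (0.0513 to 0.0677), Acadm without Chow_NCoRKO_27ac_122 or Ptulid_NCoRKO_27ac_232 (0.0617 to 0.0653), Ppargc1a without Chow_NCoRKO_27ac_122, Chow_NCoRKO_27ac_146 or Chow_NCoRKO_27ac_190 or Ptulid_NCoRKO_27ac_239 (0.0556 to 0.163) and Apoa2 without Chow_NCoRKO_27ac_122 or Chow_NCoRKO_27ac_146 or Ptulid_NCoRKO_27ac_239 (0.0744 to 0.178).

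In KO, 3269 regions differed by diet (1724 higher, 1545 lower) and 852 genes (503 higher, 349 lower). The count was 1857 and 2138 regions without Chow_NCoRKO_27ac_122 and Chow_NCoRKO_27ac_190, and 2074 and 1794 without Ptulid_NCoRKO_27ac_232 and Ptulid_NCoRKO_27ac_239, with 467, 538, 531 and 467 genes. Scaled by library totals, which shifted all regions by a median of 0.11, 2843 were higher and 1031 lower. Within the libraries of higher chrM share (1 against 3) 2098 regions differed (781 higher, 1317 lower), and the lower set held no KO chow library.

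Diet changes found in WT were mostly present in KO, whose libraries are separate. Of the 1949 regions called in WT, 1759 (90.3%) had the same sign in KO, 699 were also called with the same sign and 4 with the opposite sign, where independent lists would share 60.5. The regions higher in WT had a median log2 fold change of 0.89 there and 0.43 in KO, and the lower ones -1.12 and -0.62 (fry, adjusted p = 0.00199 and 3.88e-06). Of the 3269 called in KO, 84.8% had the same sign in WT. Within WT libraries of lower chrM share this was 82.2%, and within those of higher share 75.6%. Across all 52606 regions, which are not independent replicates, Pearson's r was 0.427 and Spearman's rho 0.375.

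KO was compared with WT on chow to ask what differs in knockout liver on this diet. Named regions that rose included those of Sult2a, Cyp3a and Mup genes and of Acot11. At an end of Sult2a3 (chromosome 7, 14121843 to 14123140) it rose from 9.18 ± 2.64 to 64.65 ± 11.34 CPM (SD, n = 3 each; log2 fold change 2.86 ± 0.31, adjusted p = 2.28e-05). It rose inside Acot11, an acyl-CoA thioesterase (chromosome 4, 106767802 to 106768566), from 5.7 ± 1.43 to 24.91 ± 0.74 CPM (2.09 ± 0.26, adjusted p = 3.28e-06). The others that rose belonged to Sult2a1, Sult2a2, Cyp3a16, Cyp3a41a, Mup-ps12 and Mup10, by 2.07 to 2.6, again with near-identical copies. The largest named loss lay 0.4 kb from Mrpl55 (chromosome 11, 59201763 to 59202323), which fell from 16.41 ± 1.79 to 3.81 ± 1.31 CPM (-2.07 ± 0.29, adjusted p = 2.28e-05). Others that fell belonged to Tmem241, Btnl10, Dhx40, Vmp1, Spsb4, Khdc1a and Clec2d, with log2 fold changes from -1.83 to -1.39. Mrpl55, Btnl10, Dhx40 and Vmp1 lie on chromosome 11 within 30 Mb of Ncor1. There 22 of 1754 regions were called lower on chow, 1.5 times the share on other autosomes, a difference that did not pass (Fisher's exact test, p = 0.0831). The Dhx40 region (adjusted p = 0.0487) did not pass with DESeq2 size factors (0.0506), the DESeq2 test (0.0641), only the groups compared (0.164) or the chrM-set term (0.0824), with 0.0183 to 0.164 over its alternatives. It was also lost without Chow_WT_27ac_96, Chow_WT_27ac_99 or Chow_WT_27ac_106 or Chow_NCoRKO_27ac_122 or Chow_NCoRKO_27ac_146 (0.0629 to 0.15).

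Lipogenic genes rose in KO on chow, 7 of 22 and none down (14 adjusted over the list alone, adjusted p = 9.63e-10, or adjusted p = 0.0667 with an estimated correlation). Among them were Scd1 (0.98 ± 0.11), the glucose-responsive factor Mlxipl (0.65 ± 0.11) and Srebf1, the sterol-responsive factor (0.63 ± 0.13). Srebf1 was lost without Chow_WT_27ac_99 (adjusted p = 0.0565) and over regions at gene ends (log2 fold change 0.39). Fasn, fatty acid synthase, rose by 0.53 ± 0.14 (adjusted p = 0.0329), but did not pass when scaled by library totals (0.0693) or cyclic loess (0.0659). Over its alternatives the log2 fold change was 0.41 to 0.59 and the adjusted p 0.00267 to 0.0693. Fasn was also lost without any 1 of Chow_WT_27ac_96, Chow_WT_27ac_99 and Chow_WT_27ac_106 and Chow_NCoRKO_27ac_122, Chow_NCoRKO_27ac_146 and Chow_NCoRKO_27ac_190 (0.0529 to 0.155). Of 16 genes induced by thyroid hormone, of which 5 are also in the lipogenesis list, 6 rose (13 adjusted over the list alone, adjusted p = 4.03e-07, or adjusted p = 0.0735 with an estimated correlation), among them Gpd2 (0.69 ± 0.13), which did not pass over regions at gene ends (0.46), and Cyp7a1 (0.7 ± 0.13). Dio1 rose by 0.66 ± 0.17 (adjusted p = 0.0313), but did not pass with library totals (0.129) or cyclic loess (0.161). Over its alternatives the log2 fold change was 0.51 to 0.79 and the adjusted p 0.00532 to 0.161. Dio1 was also lost without Chow_WT_27ac_96, Chow_WT_27ac_99 or Chow_WT_27ac_106 or Chow_NCoRKO_27ac_122 or Chow_NCoRKO_27ac_190 (0.0816 to 0.155). Of 18 female-biased genes, 6 rose (6 adjusted over the list alone, adjusted p = 2.12e-08, or adjusted p = 0.153 with an estimated correlation), among them Sult2a1 (4.8-fold) and Cyp17a1, of steroid synthesis (0.89 ± 0.15).

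Bile acid genes were higher in KO on chow (4 up, 1 down of 21; 6 and 1 adjusted over the list alone, adjusted p = 2.29e-05, or adjusted p = 0.192 with an estimated correlation). Akr1d1 rose by 0.69 ± 0.11. It did not pass over regions at gene ends (adjusted p = 0.165, with 8.78e-05 to 0.165 over its alternatives) or within 10 kb (log2 fold change 0.37). Fatty acid oxidation was higher (4 of 29; 6 adjusted over the list alone, adjusted p = 0.000305, or adjusted p = 0.429 with an estimated correlation). The clock was higher (1 of 19, Nfil3; 7 adjusted over the list alone, adjusted p = 7.97e-05, or adjusted p = 0.228 with an estimated correlation), as was the growth hormone axis (1 of 13, Bcl6; 2 adjusted over the list alone, adjusted p = 0.000952, or adjusted p = 0.227 with an estimated correlation). Cholesterol synthesis was higher (1 of 23, Sc5d; 1 adjusted over the list alone, adjusted p = 0.0129, or adjusted p = 0.345 with an estimated correlation). Glucose metabolism was higher (3 of 20; 3 adjusted over the list alone, adjusted p = 0.0165, or adjusted p = 0.491 with an estimated correlation). Xenobiotic metabolism was higher (0 of 21; 0 adjusted over the list alone, adjusted p = 0.0276, or adjusted p = 0.487 with an estimated correlation). Cholesterol did not pass without Chow_WT_27ac_99 (adjusted p = 0.0554), glucose without Chow_WT_27ac_96 (0.092) or with cyclic loess (0.564), and xenobiotic metabolism without Chow_WT_27ac_99 or Chow_NCoRKO_27ac_146 or Chow_NCoRKO_27ac_190 (0.054 to 0.206) or with cyclic loess (0.477). Over regions in place of genes the glucose and xenobiotic lists did not pass (medians 0.105 and 0.083), nor did the latter over regions at gene ends. With fry the lists of cholesterol, fatty acid oxidation, glucose and xenobiotic metabolism did not pass. The genes Nfil3 (without any but Chow_NCoRKO_27ac_122, 0.0591 to 0.128), Bcl6 (without Chow_WT_27ac_99 or Chow_NCoRKO_27ac_122, 0.0519 to 0.0654) and Sc5d (the same libraries, 0.0745 to 0.0806) were lost as well, and Nfil3 and Bcl6 did not pass with cyclic loess or over regions at gene ends. Of the 39 list genes named by rule that passed on chow, 27 were lost when 1 or more of the 6 libraries was left out.

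Kupffer, endothelial and stellate cell markers were lower in KO on chow, and hepatocyte identity genes higher (2 of 21, Foxa2 and Onecut1; 3 adjusted over the list alone, adjusted p = 8.15e-05, or adjusted p = 0.345 with an estimated correlation). With cyclic loess the hepatocyte list had a median of 0.074 in place of 0.213 and did not pass (adjusted p = 0.133; 1.37e-06 to 0.345 over its alternatives). Of 8 Kupffer cell markers, Spi1, Ptprc and C1qc fell (6 adjusted over the list alone, median -0.72; adjusted p = 9.09e-05, or adjusted p = 0.153 with an estimated correlation). Of 13 endothelial markers, Ehd3 and Pecam1 fell (6 adjusted over the list alone, median -0.44; adjusted p = 7.97e-05, or adjusted p = 0.228 with an estimated correlation). Of 7 stellate cell markers, Hgf and Col3a1 fell (2 adjusted over the list alone, median -0.51; adjusted p = 0.00387, or adjusted p = 0.345 with an estimated correlation). Cholangiocyte markers had a median of 0.22 (adjusted p = 0.548). Male-biased genes, 2 up and 2 down of 15 (3 and 4 adjusted over the list alone), had a median of 0.11 and a mean of -0.05 (adjusted p = 0.768). Receptors and coregulators, with Tbl1xr1, a subunit of the NCoR complex, higher (0.58 ± 0.1), had a median of -0.03 and a mean of -0.02 against an upward test (adjusted p = 0.863). Inflammation had a median of -0.02 and a mean of 0.01 (adjusted p = 0.863), and cell cycle -0.06 and 0.04 (adjusted p = 0.674). Lymphocyte markers (0 of 3; 2 up adjusted over the list alone, adjusted p = 0.37) and housekeeping genes (0 of 12; 0.724) did not pass. Foxa2 was lost without Chow_WT_27ac_96 or Chow_WT_27ac_99 or Chow_NCoRKO_27ac_190 (0.0546 to 0.0659), Onecut1 without Chow_WT_27ac_96 or Chow_WT_27ac_99 or Chow_NCoRKO_27ac_146 or Chow_NCoRKO_27ac_190 (0.0552 to 0.0719), Spi1 without any but Chow_WT_27ac_99 (0.0616 to 0.104) and Ptprc without any 1 of the 6 libraries (0.058 to 0.156). C1qc was lost without Chow_WT_27ac_99 or Chow_WT_27ac_106 or Chow_NCoRKO_27ac_122 or Chow_NCoRKO_27ac_190 (0.145 to 0.214), Pecam1 without Chow_WT_27ac_99 or Chow_WT_27ac_106 or Chow_NCoRKO_27ac_122 (0.0503 to 0.0782), Hgf without any but Chow_NCoRKO_27ac_122 (0.0608 to 0.125) and Col3a1 without Chow_WT_27ac_99 or Chow_WT_27ac_106 or Chow_NCoRKO_27ac_146 or Chow_NCoRKO_27ac_190 (0.102 to 0.12). With cyclic loess Foxa2, Ptprc, C1qc and Col3a1 did not pass, nor did Ehd3 and Pecam1 over regions at gene ends or Ptprc within 10 kb.

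In all, 1278 regions differed between KO and WT on chow (845 higher, 433 lower) and 454 genes (278 higher, 176 lower). Scaling decided which way most went: by library totals 387 regions were higher and 1730 lower, and without chrM-like regions 594 and 727, with all regions shifted by a median of -0.197 and -0.103; genes went 158 higher and 517 lower, and 181 and 369. The count was 799, 448 and 536 regions without Chow_WT_27ac_96, Chow_WT_27ac_99 and Chow_WT_27ac_106, and 579, 651 and 499 without Chow_NCoRKO_27ac_122, Chow_NCoRKO_27ac_146 and Chow_NCoRKO_27ac_190, with 253, 111, 184, 174, 230 and 136 genes. It was 2523 from only the 2 groups, 4008 with the chrM-set term, and 2701 (2092 higher, 609 lower) within the higher chrM set (3 against 2), since the lower set held no KO chow library.

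On PTU/LID, KO and WT were compared to ask what differs in knockout liver on this diet. Acetylation rose near Sult2a2 (chromosome 7, 13721665 to 13722635; 4.8 ± 1.1 to 32.54 ± 11.1 CPM, SD, n = 3 each; log2 fold change 2.77 ± 0.3, adjusted p = 9.48e-07). It also rose 6.3 kb from Fabp5, a fatty acid binding protein (chromosome 3, 10022596 to 10023229; 3.58 ± 0.13 to 21.93 ± 5.26 CPM; 2.6 ± 0.33, adjusted p = 4.5e-06). The others that rose belonged to Dync2li1, Acot11, Adcy1, Kcnk3, Sult2a7 and Cdk15, by 2.13 to 2.44. The largest named loss lay 6.3 kb from Dhx40 (chromosome 11, 86813749 to 86814532; -2.29 ± 0.46, adjusted p = 0.0105). Tmem241, Vmp1, Btnl10, Mrpl55, Avpr1a, Mrps23 and Nfix regions also fell, from -1.83 to -1.48, and Dhx40, Vmp1, Btnl10, Mrpl55 and Mrps23 lie within 30 Mb of Ncor1. There 11 of 1754 regions were called lower on PTU/LID, 0.89 times the share on other autosomes (Fisher's exact test, p = 0.884). The Dhx40 region did not pass without Ptulid_NCoRKO_27ac_211 or Ptulid_NCoRKO_27ac_239 (adjusted p = 0.0523 and 0.0802).

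Lipogenic genes rose in KO on PTU/LID, 13 of 22 and none down (16 adjusted over the list alone, adjusted p = 1.8e-14, or adjusted p = 0.0556 with an estimated correlation). Scd1 rose by 1.62 ± 0.11, Thrsp, a lipogenic gene induced by thyroid hormone, by 0.91 ± 0.14, Me1 by 0.86 ± 0.15, Acacb by 0.86 ± 0.13 and Elovl5 by 0.82 ± 0.11. Fasn rose by 0.51 ± 0.14 (adjusted p = 0.0266), but did not pass with library totals (0.0626). Over its alternatives the log2 fold change was 0.41 to 0.56 and the adjusted p 0.00456 to 0.0626. Fasn was also lost without Ptulid_WT_27ac_135 or Ptulid_NCoRKO_27ac_232 or Ptulid_NCoRKO_27ac_239 (0.0501 to 0.0771). Of 16 genes induced by thyroid hormone, again with 5 shared with lipogenesis, 6 rose (10 adjusted over the list alone, adjusted p = 1.76e-08, or adjusted p = 0.0667 with an estimated correlation). Gpd2 rose by 0.84 ± 0.13 but did not pass over regions at gene ends (adjusted p = 0.107, with 1.39e-05 to 0.107 over its alternatives), and Dio1 had -0.04 ± 0.19. Of 13 growth hormone axis genes, 7 rose (7 adjusted over the list alone, adjusted p = 4.63e-08, or adjusted p = 0.0735 with an estimated correlation), among them Igfbp1 (0.74 ± 0.12) and Stat5b, a factor that growth hormone activates (0.6 ± 0.1). Of 29 genes of fatty acid oxidation, 9 rose (13 adjusted over the list alone, adjusted p = 1.48e-08, or adjusted p = 0.228 with an estimated correlation), among them Acot1 (1.09 ± 0.18). Of 21 bile acid genes, 7 rose (10 adjusted over the list alone, adjusted p = 2.01e-05, or adjusted p = 0.192 with an estimated correlation), with the sterol transporters Abcg5 (0.91 ± 0.14) and Abcg8 (0.89 ± 0.12).

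Cholesterol genes were higher on PTU/LID (4 of 23, such as Sc5d at 0.8 ± 0.11; 4 up and 1 down adjusted over the list alone, adjusted p = 0.000513, or adjusted p = 0.192 with an estimated correlation). Xenobiotic genes were too (5 of 21, among them Cyp3a11 at 1.11 ± 0.12; 8 adjusted over the list alone, adjusted p = 0.000513, or adjusted p = 0.345 with an estimated correlation). So were female-biased genes (4 of 18; 9 adjusted over the list alone, adjusted p = 3.19e-06, or adjusted p = 0.192 with an estimated correlation). Glucose metabolism was higher (4 of 20, 5 adjusted over the list alone, adjusted p = 0.000679, or adjusted p = 0.345 with an estimated correlation). The clock was higher (2 of 19, 2 adjusted over the list alone, adjusted p = 0.00237, or adjusted p = 0.345 with an estimated correlation). Cell cycle was higher (1 of 7, Cdkn1a, an inhibitor of the cycle, 2 adjusted over the list alone, adjusted p = 0.0441, or adjusted p = 0.345 with an estimated correlation). Hepatocyte identity was higher (0 of 21, 0 adjusted over the list alone, adjusted p = 0.00317, or adjusted p = 0.46 with an estimated correlation). Stellate cell markers were lower (0 of 7; 0 adjusted over the list alone, median -0.45; adjusted p = 0.0366, or adjusted p = 0.472 with an estimated correlation). Kupffer cell markers had a median of 0.01 and a mean of -0.08 (adjusted p = 0.832), and endothelial markers a median of -0.13 (adjusted p = 0.106). With 1 library left out, 4 of these lists were lost. They were glucose without Ptulid_WT_27ac_135 (adjusted p = 0.108), hepatocyte identity without Ptulid_WT_27ac_135 (0.113) and cell cycle without any but Ptulid_WT_27ac_135 (0.0529 to 0.229). The other was stellate cells without Ptulid_WT_27ac_135 or Ptulid_WT_27ac_155 or Ptulid_NCoRKO_27ac_232 or Ptulid_NCoRKO_27ac_239 (0.0636 to 0.14). Cdkn1a was lost without Ptulid_WT_27ac_280 or Ptulid_NCoRKO_27ac_232 or Ptulid_NCoRKO_27ac_239 (0.0609 to 0.161), with library totals and within 10 kb. With cyclic loess hepatocyte identity had an adjusted p of 0.989 and glucose 0.158, and with the chrM-set term stellate cells had 0.0569 and cell cycle 0.0649. Over regions in place of genes the cholesterol (median 0.068) and cell cycle (0.173) lists did not pass. Stellate cells did not pass with cyclic loess (-0.237), library totals or regions at gene ends (-0.272), nor cell cycle at gene ends, nor the clock with cyclic loess (0.105). With fry the glucose, clock, cell cycle, hepatocyte and stellate lists did not pass.

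Tbl1xr1 rose by 0.76 ± 0.1 on PTU/LID too (2 up of 17 receptors and coregulators, 3 adjusted over the list alone, adjusted p = 0.364 for the list). Mup1 rose by 0.63 ± 0.14 among male-biased genes (1 up of 15, or 3 up and 3 down adjusted over the list alone, list adjusted p = 0.851). Over regions at gene ends (adjusted p = 0.375) or within 10 kb Mup1 did not pass. Ccl2 had -0.58 ± 0.16 among 13 inflammation genes (1 down; 1 up and 1 down adjusted over the list alone, adjusted p = 0.909). Ccl2 was lost without Ptulid_WT_27ac_135 or Ptulid_WT_27ac_280 or Ptulid_NCoRKO_27ac_232 or Ptulid_NCoRKO_27ac_239 (0.0857 to 0.11), with cyclic loess, over regions at gene ends and within 10 kb. Lymphocytes (0 of 3; 1 up adjusted over the list alone, adjusted p = 0.557), cholangiocytes (0 of 5; 0.903) and housekeeping genes (0 of 12; 0.863) did not pass. Of the 42 list genes named by rule that passed on PTU/LID, 11 were lost when 1 or more of the 6 libraries was left out. Median, mean and test differed in sign for receptors and coregulators (-0.03, 0.06, upward), male-biased genes (-0.05, 0.003, downward), inflammation (0.015, -0.002, upward) and cholangiocytes (-0.07, -0.09, upward), none of which passed.

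In all, 2032 regions differed between KO and WT on PTU/LID (1665 higher, 367 lower) and 719 genes (559 higher, 160 lower). The count was 1012, 1094 and 929 regions without Ptulid_WT_27ac_280 and Ptulid_NCoRKO_27ac_232 and Ptulid_NCoRKO_27ac_239, with 412, 363 and 383 genes. It was 1304 from only the 2 groups and 3380 with the chrM-set term. By library totals without chrM-like regions 1266 were higher and 609 lower, and the genes went 355 higher and 407 lower (351 and 375 by library totals). Within the lower chrM set (2 against 2) 3361 regions differed (2696 higher, 665 lower), and within the higher set (1 against 1) 522 (408 higher, 114 lower).

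Of the 1278 regions called on chow, 83.7% had the same sign on PTU/LID, in separate libraries, and of the 2032 called on PTU/LID, 81.2% had it on chow. Both comparisons called 313 with the same sign and 5 with opposite signs, where independent lists would share 29.8. Regions higher in KO on chow had a median log2 fold change of 0.93 there and 0.51 on PTU/LID, and lower ones -1.2 and -0.31 (fry, adjusted p = 0.000331 and 0.002). Within the lower chrM set 84.4% of the regions called on chow had the same sign on PTU/LID, and within the higher set 68.7%. Within the higher set 81.8% of those called on PTU/LID had it on chow. Across all regions r was 0.328 and rho 0.316. Mean total counts were higher in KO than in WT on both diets (6347161 against 4087936 on chow, 6073347 against 4123762 on PTU/LID). Agreement between diets therefore does not part genotype from total counts.

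**Figure D3:**
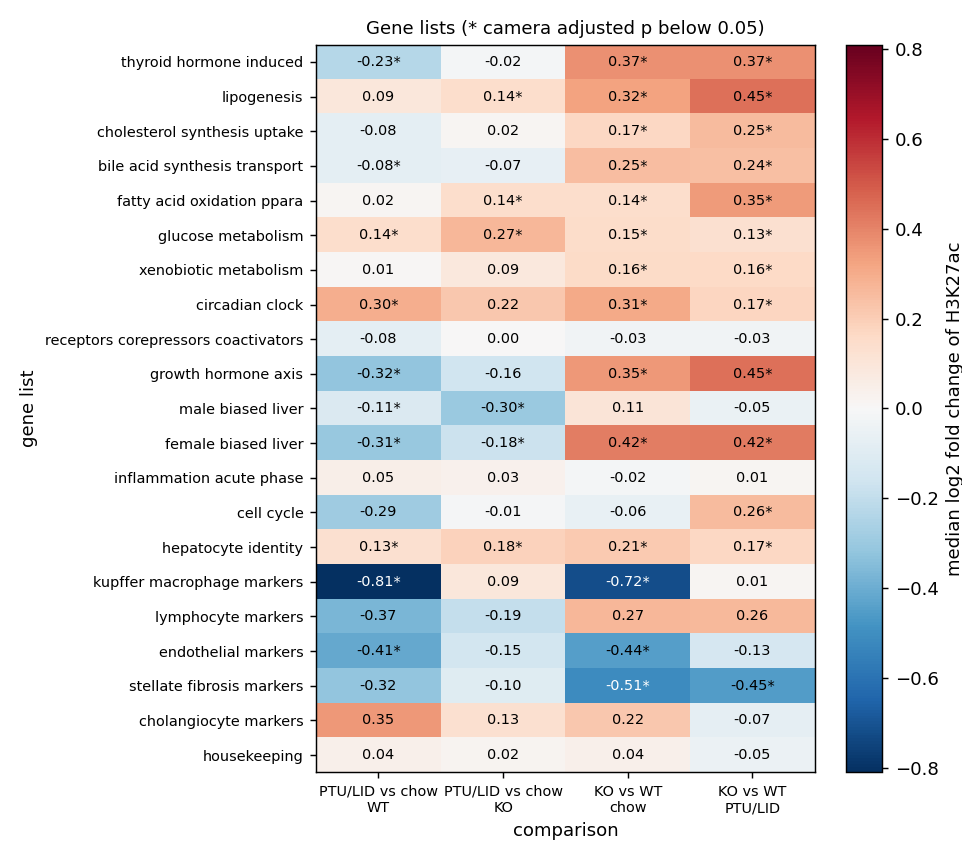
Median log2 fold change of each of the 21 gene lists (one line each) in the 4 comparisons of 2 groups (one column each), as a colour scale, with a star where the list test had an adjusted p below 0.05 at a preset correlation. Lipogenesis had medians of 0.32 on chow and 0.45 on PTU/LID for KO against WT, and Kupffer cell markers -0.72 and 0.01.

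The interaction asks whether the effect of diet differed between genotypes. It passed in 121 of 52606 regions (83 higher, 38 lower) and 46 of 11446 genes (34 higher, 12 lower). A region inside Cmah (chromosome 13, 24364133 to 24366323) went from 50.77 ± 8.86 to 17.53 ± 4.07 CPM in WT and from 21.65 ± 4.2 to 37.13 ± 4.64 in KO (SD, n = 3 each; interaction 2.3 ± 0.28, adjusted p = 2.04e-05). The Fabp5 region had 4.84 ± 2.57 and 3.58 ± 0.13 CPM in WT and 4.86 ± 2.28 and 21.93 ± 5.26 in KO (2.52 ± 0.5, adjusted p = 0.0163). Positive interactions were also named inside Dync2li1, Zfp970 and Ppp1r3g, a glycogen-targeting phosphatase subunit, and negative ones at Cyp3a16, Cyp3a41a, Cyp3a41b, Mup9 and Mup10, from -3.08 to -2.24. The Fabp5 region was lost without Chow_WT_27ac_99, Chow_NCoRKO_27ac_122 or Chow_NCoRKO_27ac_190 or Ptulid_NCoRKO_27ac_239 (adjusted p = 0.0548 to 0.139) and Zfp970 without Chow_WT_27ac_106 or Ptulid_NCoRKO_27ac_232 (0.0578 to 0.0725). Cyp3a41b was lost without Chow_WT_27ac_96 or Chow_WT_27ac_106, Ptulid_WT_27ac_155, Chow_NCoRKO_27ac_122 or Chow_NCoRKO_27ac_146 or Ptulid_NCoRKO_27ac_232 or Ptulid_NCoRKO_27ac_239 (0.0663 to 0.127), and Cyp3a41a without Chow_WT_27ac_106, Ptulid_WT_27ac_135 or Ptulid_WT_27ac_155, Chow_NCoRKO_27ac_146 or Chow_NCoRKO_27ac_190 or Ptulid_NCoRKO_27ac_232 (0.0576 to 0.127). Me1 (0.54 ± 0.21, adjusted p = 0.371), Thrsp (0.52 ± 0.19, 0.335) and Dio1 (-0.7 ± 0.25, 0.32) did not pass.

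Of the lists, 4 passed, all upward. These were Kupffer cell markers (median 0.77, adjusted p = 0.00145, or adjusted p = 0.192 with an estimated correlation) and endothelial markers (0.32, adjusted p = 0.0344, or adjusted p = 0.487 with an estimated correlation). The others were the growth hormone axis (0.16, adjusted p = 0.0151, or adjusted p = 0.345 with an estimated correlation) and lipogenesis (0.09, adjusted p = 0.0325, or adjusted p = 0.399 with an estimated correlation). None of their genes passed over all genes. Adjusted over the list alone, Spi1 (0.93 ± 0.26), Scd1 (0.64 ± 0.16) and Elovl5 (0.57 ± 0.15) did. The Kupffer interaction uses the same WT chow libraries as the calls for diet in WT and for KO on chow. Endothelial markers did not pass without Chow_WT_27ac_96 or Chow_WT_27ac_99, Ptulid_WT_27ac_155 or Ptulid_WT_27ac_280, Chow_NCoRKO_27ac_190 or Ptulid_NCoRKO_27ac_211 or Ptulid_NCoRKO_27ac_239 (adjusted p = 0.0576 to 0.177). The growth hormone axis did not pass without Chow_WT_27ac_96, Ptulid_WT_27ac_135, Chow_NCoRKO_27ac_190 or Ptulid_NCoRKO_27ac_232 (0.0533 to 0.11), and lipogenesis without Chow_WT_27ac_106, Ptulid_WT_27ac_135, Chow_NCoRKO_27ac_122 or Ptulid_NCoRKO_27ac_232 or Ptulid_NCoRKO_27ac_239 (0.065 to 0.211) or with the chrM-set term (0.123). Over regions at gene ends the growth hormone axis had a median of 0.01 and did not pass. Endothelial markers and lipogenesis did not pass with cyclic loess, nor lipogenesis over regions in place of genes, and with fry none of these 3 lists passed.

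Female-biased genes had 1 member past the threshold, Cyp3a16 (-2.09 ± 0.38, adjusted p = 0.038; 1 adjusted over the list alone, median -0.015, list adjusted p = 0.413), which was lost without Chow_WT_27ac_99, Ptulid_WT_27ac_135, Ptulid_WT_27ac_155 or Ptulid_WT_27ac_280, Chow_NCoRKO_27ac_146 or Chow_NCoRKO_27ac_190 or Ptulid_NCoRKO_27ac_239 (0.0663 to 0.165), with library totals or cyclic loess, and over regions at gene ends or within 10 kb. No member of the other lists passed the interaction over all genes. Their adjusted p was 0.0521 for fatty acid oxidation (1 up adjusted over the list alone), 0.12 for xenobiotic metabolism (1 up), 0.532 for genes induced by thyroid hormone, 0.407 for cholesterol, and 0.733 for bile acids. It was 0.413 for glucose, 0.548 for the clock, and 0.449 for receptors and coregulators. It was 0.228 for cell cycle, 0.42 for hepatocyte identity, 0.544 for stellate cells and 0.596 for housekeeping genes. Median, mean and test differed in sign for male-biased genes (-0.106, 0.051, downward; 0.544), inflammation (0.045, -0.014, downward; 0.909), cholangiocytes (0.048, -0.136, downward; 0.724) and lymphocytes (-0.014, 0.09, downward; 1 lower adjusted over the list alone; 0.832).

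Region counts of the interaction without 1 library were 59 and 33 (Chow_WT_27ac_99 and Chow_WT_27ac_106), 208 and 74 (Ptulid_WT_27ac_135 and Ptulid_WT_27ac_280), 57 and 54 (Chow_NCoRKO_27ac_122 and Chow_NCoRKO_27ac_190) and 55 and 37 (Ptulid_NCoRKO_27ac_232 and Ptulid_NCoRKO_27ac_239). Gene counts were 20, 30, 89, 19, 14 and 20 for the first 6 of these and 24 for the last. With library totals, where all regions had a median of 0.133, 254 regions were higher and 34 lower, and with the chrM-set term 250 and 273.

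Averaged over genotypes, 5954 regions differed by diet (3062 higher, 2892 lower) and 1824 genes. Named regions that rose belonged to Osbpl5, Khdc1a, Thap7, Iqck and Rassf3 (1.85 to 2.37), and those that fell to Mup2, Mup11, Mup12, Mup17 and Dio1 (chromosome 4, 107300090 to 107301558; -2.58 ± 0.2, adjusted p = 7.39e-12). Averaged over diets, 4230 regions differed by genotype (2930 higher, 1300 lower) and 1323 genes. Sult2a1, Sult2a2, Sult2a3, Cdk15 and Scd1 regions rose in KO, the last 11.6 kb from the gene (chromosome 19, 44418252 to 44420331) by 1.74 ± 0.15 (adjusted p = 5.53e-10). Dhx40, Mrpl55, Tmem241, Btnl10 and Vmp1 regions fell, from -1.99 to -1.67, all but Tmem241 within 30 Mb of Ncor1. By library totals the diet calls were 65.1% higher in place of 51.4%, and the genotype calls 31.6% in place of 69.3% (45.9% without chrM-like regions), with all regions shifted by a median of -0.143 and -0.101 for genotype. Without Ptulid_NCoRKO_27ac_232 and Ptulid_NCoRKO_27ac_239 the genotype count was 2623 and 2751.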

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

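The tests on regions near Ncor1 and on marker lists were chosen only after their results were seen, as was the 2% division by chrM share that the tests within sets use. The effect of diet differed between genotypes in 121 regions and 46 genes. Among the named regions the interaction log2 fold change was 1.24 and 1.54 at 2 regions near Sult2a7, 1.15 and 1.5 at 2 near Khdc1a, 1.66 near Oma1, 2.52 near Fabp5, 2.12 and 2.23 inside Dync2li1, 2.3 inside Cmah, 2.11 inside Zfp970 and 2.07 inside Ppp1r3g. It was -1.96 in Mup-ps12, -1.59 near Mup17, -2.45 and -1.96 near Mup10, -2.26 near Mup9, -2.76 and -3.08 at 2 regions of Cyp3a16, -2.24 at Cyp3a41a, -2.35 at Cyp3a41b and -2.21 near Akr1d1. The gene Cyp3a16 had -2.09, which did not pass with library totals (adjusted p = 0.0782), cyclic loess (0.0562), or regions at gene ends (0.0882) or within 10 kb (0.0524), with 0.000332 to 0.0882 over its alternatives and values from -2.22 to -1.94. The lists that passed at a preset correlation had interaction medians of 0.77 (Kupffer cell markers), 0.32 (endothelial markers), 0.16 (growth hormone axis) and 0.09 (lipogenesis), with adjusted p = 0.192, 0.487, 0.345 and 0.399 with an estimated correlation. With fry the last 3 did not pass, and they were lost when 1 of 7, 4 and 5 libraries, in that order, was left out.

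Regroupings of the libraries gave 1 split in 25 with as many interaction calls, the real one, with 121 regions against at most 108 in the others and 46 genes against at most 14. These draws shuffled diet within each genotype, which also breaks up the effect of diet and adds it to the spread within groups. They therefore cannot tell whether the interaction calls exceed chance. The margin over regions is small, and the draw with 108 shows that a structure of the libraries other than the groups can call nearly as many. For the mean effects, 1 of 25 had as many, the real one, with 5954 regions against 339 for diet and 4230 against 528 for genotype. Each comparison of 3 with 3 libraries has only 10 splits, too few for a share under 0.05, and in each 1 split, the real one, had as many. The real value and the highest other were 1949 and 331 regions (880 and 46 genes) for diet in WT, 3269 and 1 (852 and 0) for diet in KO, 1278 and 0 (454 and 0) for KO on chow, and 2032 and 4 (719 and 2) for KO on PTU/LID. The split with 331 set Chow_WT_27ac_96 and Chow_WT_27ac_99 and Ptulid_WT_27ac_135 against the rest, which follows the chrM share. The same split follows total counts (2965505 to 3466932 against 4546159 to 5831372). It also follows the share of nuclear counts in the top 1% of regions (9.46% to 9.64% against 10.69% to 11.15%). These measures cannot be told apart here.

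The first pattern is the effect of diet, since chrM share was lower on PTU/LID. If the chrM sets were its whole cause, regions called by diet in KO would have no common direction in WT within a set. They had the same sign in 82.2% within the lower set (fry, adjusted p = 0.002 higher and 0.000331 lower) and in 75.6% within the higher set (adjusted p = 0.0201 and 0.00055), with 1 library on 1 side in each set, assumed to vary like the others. As far as that assumption holds, this argues against the sets as the whole cause, and a part from them stays open. Hypothyroidism, which the design names, stays open.

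The second pattern is the place of regions lower in KO, where a first test of gathering near Ncor1 over all calls did not pass (3.08% of regions within 30 Mb against 2.5% on other autosomes, ratio 1.23, Fisher's exact test, p = 0.14), nor did the calls on chow (p = 0.0831) or PTU/LID alone (p = 0.884), and 2 sets of calls at 5 cutoffs were looked at after it, with ratios from 1.24 (p = 0.119) to 38.04 (p = 4.23e-05) and a lowest p of 1.21e-07, as were comparisons set aside because they counted the gathered regions again. Of the 36 regions called lower on both diets 7 lay there, in 5 stretches of 1 Mb and so not independent, where 1.2 would be expected (Fisher's exact test, p = 0.000178), and no other window of 60 Mb held more than 4, while 13 regions higher on both diets lay there, which did not pass (p = 0.239). Among regions called lower on chow alone, taken as 1 value per stretch of 1 Mb, the median on PTU/LID was -0.5 near Ncor1 and -0.29 elsewhere, a difference of -0.21 that did not pass (permutation p = 0.12), and those called lower on PTU/LID alone differed on chow by 0.22 (permutation p = 0.231), so DNA of another strain, carried along with the targeted allele, stays open as a possible explanation. Of regions called on 1 diet 29.7% were lower near Ncor1 against 26.9% elsewhere (Fisher's exact test, p = 0.669), which leaves open fewer reads mapped from variant DNA. An effect of the knockout on nearby genes stays open too, as no sequence was used here and the labels give C57BL/6J for both genotypes, so losses at Mrpl55, Btnl10, Dhx40, Vmp1, Mrps23 and Slfn8 may not reflect NCoR1 itself.

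The third pattern is lower acetylation of Kupffer, endothelial and stellate cell markers in KO on chow, with the hepatocyte list higher, at a preset correlation. With an estimated correlation none passed (adjusted p = 0.153, 0.228, 0.345 and 0.345 in that order), nor did the hepatocyte list with cyclic loess (median 0.074). Kupffer markers had medians of -0.81 by diet in WT and -0.72 in KO on chow. Without WT chow libraries the medians were 0.09 by diet in KO and 0.01 for KO on PTU/LID. The Kupffer calls for diet in WT, KO on chow and the interaction all use the same 3 WT chow libraries, so they are not separate findings. A lower share of all other cell types alike would lower cholangiocyte markers too. Their mean of 0.05 ± 0.19 (SEM over genes) differed from the -0.8 ± 0.07 of Kupffer markers by 0.85 (SE 0.2). These were the highest and lowest of 4 lists, and genes of the same libraries are not independent replicates. Only 5 of 11 cholangiocyte and 8 of 18 Kupffer markers had a region. An earlier criterion on medians, also chosen afterwards, pointed the same way. Neither can decide whether all other cell types fell alike. A lower share of Kupffer, endothelial and stellate cells could still account for the pattern, as could a change within those cells, and no value here separates these.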

How the results depend on the processing

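The tests with the chrM-set term, without chrM-like regions, with library totals after removing them, and with cyclic loess at gene level were chosen after seeing the data. No paired analysis was possible because the H3K27ac groups share no replicate numbers. A GC correction and a comparison with input were planned and not run, and fits of only the groups compared apply to comparisons of 2 groups. The cause of each change below was not tested unless fewer libraries or regions give it. None of the 94 named region calls and 47 passing list tests changed direction under the alternatives run for them (for lists not DESeq2 size factors, regions within 10 kb or library totals without chrM-like regions), and lists were lost in 13 cases with cyclic loess, 8 with the chrM-set term, 7 each over regions at gene ends and over regions in place of genes, and 1 with library totals. Among genes Ghr (0.09) and Ccl2 (-0.11) reversed for diet in WT over regions at gene ends, Ccl2 also within 10 kb (-0.08), and Ccl2 in KO in both (-0.43 and -0.43). With library totals, KO on chow gave 2117 regions, the interaction 288 regions and 79 genes, and 75.2% of KO effects carried over between diets. With only the groups compared, KO on chow gave 2523 and KO on PTU/LID 1304. With the chrM-set term, region counts were 4008 (KO on chow), 3380 (KO on PTU/LID), 523 (interaction), 3885 (mean diet) and 6892 (mean KO), gene counts 1537, 1142 and 213 for the first 3, and 84.0% of diet effects carried over. Cyclic loess gave 182 interaction regions. Regions at gene ends, which are fewer, gave 409, 381, 229, 368 and 19 genes for diet in WT, diet in KO, KO on chow, KO on PTU/LID and the interaction. Of 105 list tests, 0 passed with an estimated correlation and 31 with fry, against 47. At adjusted p below 0.01, 96.1% of diet effects carried over.

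With 1 library left out, regions ranged from 669 to 3612 (diet in WT), 1794 to 3602 (diet in KO), 448 to 799 (KO on chow), 929 to 2599 (KO on PTU/LID), 33 to 208 (interaction), 4261 to 7816 (mean diet) and 2623 to 5666 (mean KO). Genes ranged from 337 to 1582, 467 to 1172, 111 to 253, 363 to 1007 and 14 to 89 in the first 5, and lists from 40 to 50. Leaving out 1 library ended 27 calls of named regions, 299 of list genes and 46 of lists, counted once per library. Shares carried over ranged from 86.1% to 94.9% for diet, 78.1% to 83.5% for KO effects called on PTU/LID and 79.6% to 88.2% for those called on chow. In simulations of diet in WT with 3 libraries per group at this depth, 4.4% of regions changed 1.5-fold were recovered, and depth alone was not varied.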

Other observations

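The gene families here were picked by a scan of name stems after the data were examined, and none passed with an estimated correlation (lowest adjusted p = 0.209). The Mup genes, which encode major urinary proteins, moved in opposite ways with diet and genotype. Of 23 measured, 19 fell and 1 rose on PTU/LID in WT (median log2 fold change -1.53), 21 fell and 1 rose in KO (-2.12), and 18 rose in KO against WT on chow (1.05) and 8 on PTU/LID (0.53), where 5 passed with library totals, 6 with the chrM-set term and 4 with cyclic loess. Of 8 Sult2a genes, 2 fell on PTU/LID in WT (median -0.26), and all 8 rose in KO on chow (median 1.51) and 7 on PTU/LID (1.42). Of 8 Cyp3a genes, 5 rose in KO on chow (0.84) and 4 fell on PTU/LID in KO (-0.73). These medians kept their sign with library totals, DESeq2 size factors, cyclic loess and the chrM-set term. Members of each family are near-identical copies, so the number of independent changes is uncertain.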
